A study of Mus musculus with 6 samples.

How the data were processed

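Adrenal glands of adult virgin female mice of strain B6.FVB were profiled on Illumina bead arrays, with 3 samples labelled as conditional knockouts of Gata6 and 3 as controls. Per the labels' protocols, total RNA came from a Qiagen RNeasy mini kit and was turned into biotin-labelled cRNA with an Ambion MessageAmp kit. The scanner software, the background subtraction and the deletion driver are not given in the sources used here.

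The deposited signals are linear probe intensity values that were not normalized between arrays, per the file headers. Between 30.7% and 33.4% of the values of an array lay below 0, so a background had been subtracted before deposit. Each signal comes with a deposited detection p-value, per the file headers. The deposited series matrix holds intensity values of the same arrays on a linear scale. Each of its columns ranked the probes as the signals of its own sample did (Spearman rho 1), and the sorted values of its first column, the 1 compared, matched the mean of the sorted signals to within 0.118. The medians of its columns lay between 9.98 and 10.05. It was used as an alternative source of values, and the method the authors used for it is not stated.

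Starting from the signals, the background was corrected with the normexp method of limma 3.58.1 in R 4.3.3, using the background spread derived from the detection p-values and an offset of 16, and the log2 values were quantile normalized. The offset pulls the changes of dim probes toward 0. Probes with a detection p-value under 0.05 on at least 3 of the 6 arrays were kept, which left 19210 of 45281. Probe symbols came from the deposited file. They were brought up to date with a RefSeq gene table of assembly GRCm38.p6, where 27740 probes matched by current symbol, 8037 by an older one and 9504 by neither, and these kept the file's name. In 40 probes the symbol had been turned into a date. A gene was represented by its tested probe with the highest mean over all 6 arrays. Among the changed genes 299 had more than 1 tested probe, and in 31 of them a probe had the opposite sign.

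Groups were compared with limma's linear model and empirical Bayes variance with an intensity trend, without covariates, two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the tested probes. The threshold was an adjusted p under 0.05. Differences are log2 values, arrays labelled cKO minus control. A gene with 0 detected arrays in one group has only a bound there. Its fold is the bright group's mean against the mean, over the dim group's arrays, of the higher of the lowest detected signal and the probe's own. A standard error of a gene's difference comes from the model. That of a list median, or of a difference between list medians, comes from the spread over genes taken as independent. It holds no spread between arrays and is too small where genes vary together.

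Before the data were examined, 33 gene lists were fixed: GATA family and cofactors, adrenocortical steroidogenesis, cholesterol biosynthesis, X-zone, zona glomerulosa, capsule and mesenchyme, extracellular matrix, ovarian and testicular somatic genes, steroid hormone receptors, hedgehog, Wnt, and TGF-beta, activin and BMP signalling, cell cycle, p53 targets and apoptosis, oxidative stress and glutathione, oxidative phosphorylation, ribosomal proteins, immediate early and heat shock genes, glucocorticoid-responsive genes, and markers of chromaffin cells, macrophages, antigen presentation, lymphocytes, mast cells, endothelium, erythroid cells, fat cells, kidney, oocytes, Schwann cells and nerve, skeletal muscle and epithelium. They held 722 genes, of which 534 were measured. Lists with at least 3 measured genes were tested with camera at a preset correlation of 0.01 between genes, adjusted over 32 lists. Camera with an estimated correlation and fry were run beside it. Fry asks whether the genes of a list move one way on balance and does not compare them with other genes. Counts of genes are given over all genes tested and adjusted over the list alone.

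Named genes followed a rule fixed before the data were examined: Gata6, the 8 largest rises and the 8 largest falls among changed genes whose groups did not overlap, up to 3 changed genes per list with the largest change or else the brightest gene, and 12 further genes of the adrenal and gonads together with the GATA genes. Genes with clone or predicted names were left out. This was applied to the current symbol, which let in Ssu2, known to the array by a clone name; that reading was settled after the values had been seen. Cyb5b, Fdxr, Rspo3, Sparc, Th and Chga were named after their values had been seen. A gene that this rule selected is not reported here.

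The group test and the list test were tried on simulated data, with 200 probes changed in each of 5 runs. These data were made from the normalized values of the tested probes, so the background correction, normalization and filter were not tried. Noise was drawn independently for each probe. Of changes of 0.5, 1, 2 and 3 log2 units, 12.4%, 61.2%, 93.2% and 98.4% were called, and 4.60% of all calls were false. A list raised by 1 log2 unit in every gene was called in 5 of 5 runs, and 2 calls over all runs were of other lists. Smaller list shifts, such as most of those reported below, were not tried. Genes of some real lists vary together, so these rates may not hold for the real lists. The depth of a bead array has no count. Alternatives covered the background correction, the normalization, the deposited matrix, the filter on dim probes, the variance model, array weights, the replicate number as a block, the averaging of probes and leaving out each array. A block for slide position was not run, as slides are not given in the sources used here. Plots were drawn with matplotlib 3.10.9.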

Results

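Gene expression was measured in whole adrenal glands of adult virgin female mice on Illumina bead arrays. The labels give 3 samples from mice with a conditional knockout (cKO) of Gata6 in the adrenal gland and 3 samples from control mice. Gata6 is a zinc finger transcription factor of the GATA family. The comparison asks which adrenal transcripts differ when Gata6 has been deleted in the gland. Each array carried 45281 probes, and between 18314 and 19459 of them were detected per array. Of these, 19210 probes for 13327 genes were bright enough to be tested. The labels do not say that the samples came from separate animals, so the p-values measure only the spread between these samples, which may be technical. The number of arrays, 3 per group, limits the precision of every value. Over the tested probes, which are not independent of one another, each array correlated with the arrays of its own label at a Pearson r of at least 0.986 and with arrays of the other label at no more than 0.978.

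Gata6 itself was measured first. Its 1 probe read 11.72 ± 0.07 log2 units (SD, n = 3) on the control arrays and 12.12 ± 0.17 on the arrays labelled cKO. The difference was 0.40 (SE 0.10), higher rather than lower on the arrays labelled cKO, and it did not pass the threshold (limma, adjusted p = 0.0545). Under median scaling it was 0.21 (adjusted p = 0.230). It passed with a robust variance (0.40, adjusted p = 0.0472), with array weights (0.43, adjusted p = 0.0330) and without cKO replicate 1 (0.46, adjusted p = 0.0448). All 3 arrays labelled cKO, at 11.99, 12.06 and 12.31, lay above the highest control array, at 11.80. The Gata6 signal therefore goes against the label. The position of the probe relative to the deleted part of the gene is not given in the sources used here, so it may check nothing, and each direction below is that of the arrays labelled cKO against the arrays labelled control. Of the other GATA genes, Gata2 read 0.62 higher (SE 0.17, adjusted p = 0.0700) and Gata3 0.33 higher (SE 0.15, adjusted p = 0.245), and neither passed. Gata2 passed with array weights (0.70, adjusted p = 0.0375) and without cKO replicate 1 (0.77, adjusted p = 0.0313). Their cofactor Zfpm2 differed by 0.11 (SE 0.12). Gata1, Gata4 and Gata5 were detected on 0 of the 6 arrays.

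On the arrays labelled cKO the X-zone markers Pik3c2g and Akr1c18 fell, and so did 16 of 20 genes of cholesterol synthesis, while 11 of 17 genes of the capsule and mesenchyme, 5 of 11 of hedgehog signalling, 7 of 26 of chromaffin cells and 6 of 16 of fat cells rose. These lists, X-zone aside, passed with a preset correlation, but with an estimated correlation the adjusted p was 0.239 for the cholesterol, capsule and hedgehog lists, adjusted p = 0.323 for chromaffin cells and adjusted p = 0.476 for fat cells. In all, 578 genes were higher and 352 lower on the arrays labelled cKO, together 6.98% of the genes tested. The median change over all genes was -0.013. At probe level, 753 probes were higher and 494 lower. Of the changed genes, 219 were higher and 106 lower by at least 2-fold. In all 930 changed genes the 3 arrays of one label lay entirely on one side of the other 3. With 3 arrays per group a call at this threshold all but requires that, so it adds no support. Such a separation was seen in 29.0% of all genes tested, where chance alone gives 10% for a single gene. Genes vary together, and the share was not computed for other groupings of the arrays, so this gap is not a test. Under median scaling in place of quantile normalization, 51.2% of the called genes were higher, against 62.2% here. The count was 601 genes without control replicate 1, 439 without control replicate 2, 502 without cKO replicate 2 and 398 without cKO replicate 3.

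**Figure D1:**
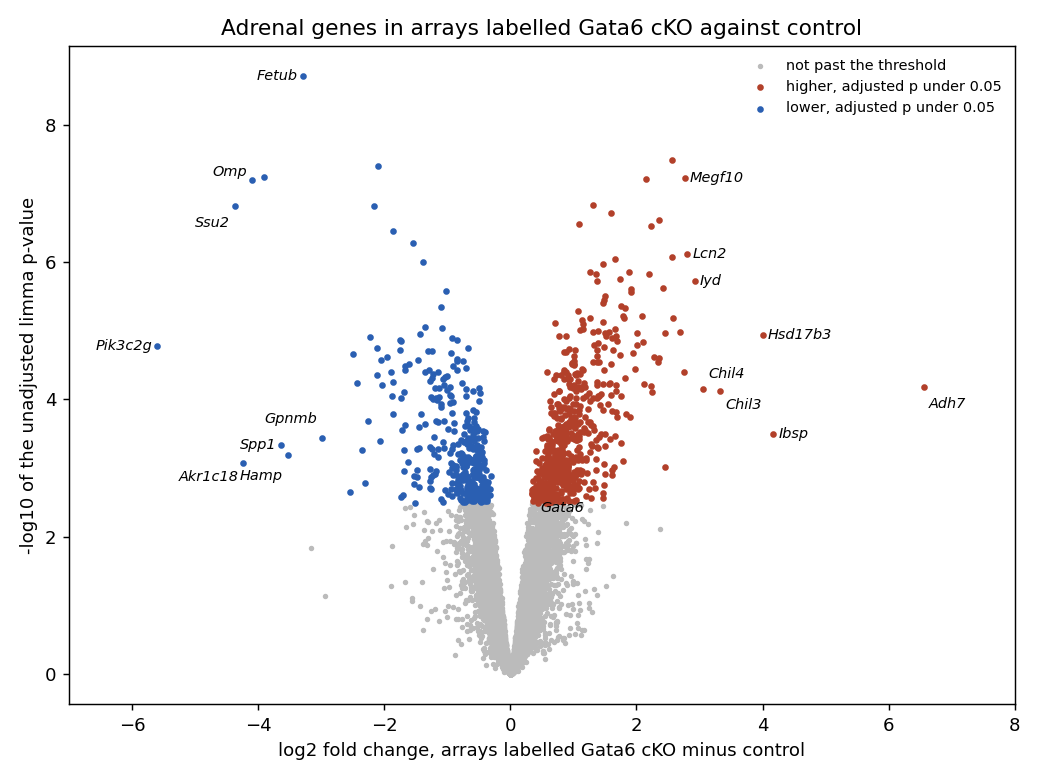
Each point is 1 gene, with the log2 fold change (arrays labelled Gata6 cKO minus control, 3 arrays each) on the horizontal axis and -log10 of the unadjusted limma p-value on the vertical axis. The 578 higher and 352 lower genes are coloured, the genes named are those with the largest changes, and Gata6 lies at 0.40, just under the threshold.

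Markers of the X-zone were among the steepest falls. This is the inner cortical zone of virgin female mice that regresses in pregnancy. Pik3c2g, a phosphoinositide kinase gene and marker of this zone, fell by 5.60 on the log2 scale (SE 0.66, adjusted p = 0.00319), and its 3 tested probes read from -5.60 to -4.03. Its brightest probe was detected on 2 of the 3 arrays labelled cKO, so the size of the fall rests partly on background signal. Akr1c18, the enzyme that inactivates progesterone, fell by 4.24 (SE 0.85, adjusted p = 0.0235). It read between 14.12 and 14.44 on the control arrays and 12.37, 8.12 and 9.63 on the arrays labelled cKO. The call on Akr1c18 was lost when control replicate 1, 2 or 3 or cKO replicate 3 was left out, at adjusted p-values of 0.0598, 0.0774, 0.0556 and 0.0934. Of the 3 X-zone markers listed, 2 were measured and both fell, over all genes and adjusted over the list alone, which is too few for a list test. Other steep falls were those of Ssu2 (-4.37, SE 0.29), of the olfactory marker protein Omp (-4.10, SE 0.24), of the osteopontin gene Spp1 (-3.63, SE 0.67), of the hepcidin gene Hamp (-3.53, SE 0.68), of the fetuin gene Fetub (-3.29, SE 0.13) and of the lysosomal glycoprotein gene Gpnmb (-2.99, SE 0.53). Ssu2 was likewise detected on 2 of the 3 arrays labelled cKO. Gpnmb was detected on all 3 but averaged 5.32 there, just above their lowest detected signals of 5.11 to 5.13. The sizes of both falls therefore rest partly on background signal, and the other Gpnmb probes were too dim to be tested. Fetub had the smallest adjusted p of all genes, 3.7e-05. The falls of Spp1 and Hamp did not pass without control replicate 2 (adjusted p = 0.0517 and 0.0694), without cKO replicate 2 (0.0574 and 0.0712) or without cKO replicate 3 (0.0703 and 0.0842), and that of Gpnmb without cKO replicate 3 (0.0609).

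The largest rise was that of Adh7, an alcohol dehydrogenase that oxidizes retinol, at 6.56 (SE 0.92, adjusted p = 0.00558). Adh7 read between 12.14 and 12.42 on the arrays labelled cKO. Among controls it was detected on 1 array, replicate 2, at 8.43, and the others lay at 4.45 and 4.35. The bone sialoprotein gene Ibsp rose by 4.17 (SE 0.72) and Hsd17b3, which makes testosterone from androstenedione, by 4.01 (SE 0.45, adjusted p = 0.00267). Ibsp did not pass without cKO replicate 3 (adjusted p = 0.0534). The chitinase-like genes Chil3 and Chil4 rose by 3.32 and 3.05, and since their sequences are nearly identical their probes may read both. Iyd, an iodotyrosine deiodinase, rose by 2.93, the lipocalin gene Lcn2 by 2.81 and the engulfment receptor gene Megf10 by 2.76. Iyd was detected on 1 control array, and Ibsp, Chil3, Chil4 and Lcn2 on 2 each, so the sizes of these rises rest partly on background signal. Megf10 was detected on all 3 control arrays but averaged 5.73 there, and Hsd17b3 read 5.42 on control replicate 3. Both values lie near the background, so the sizes of these rises are uncertain too.

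**Figure D2:**
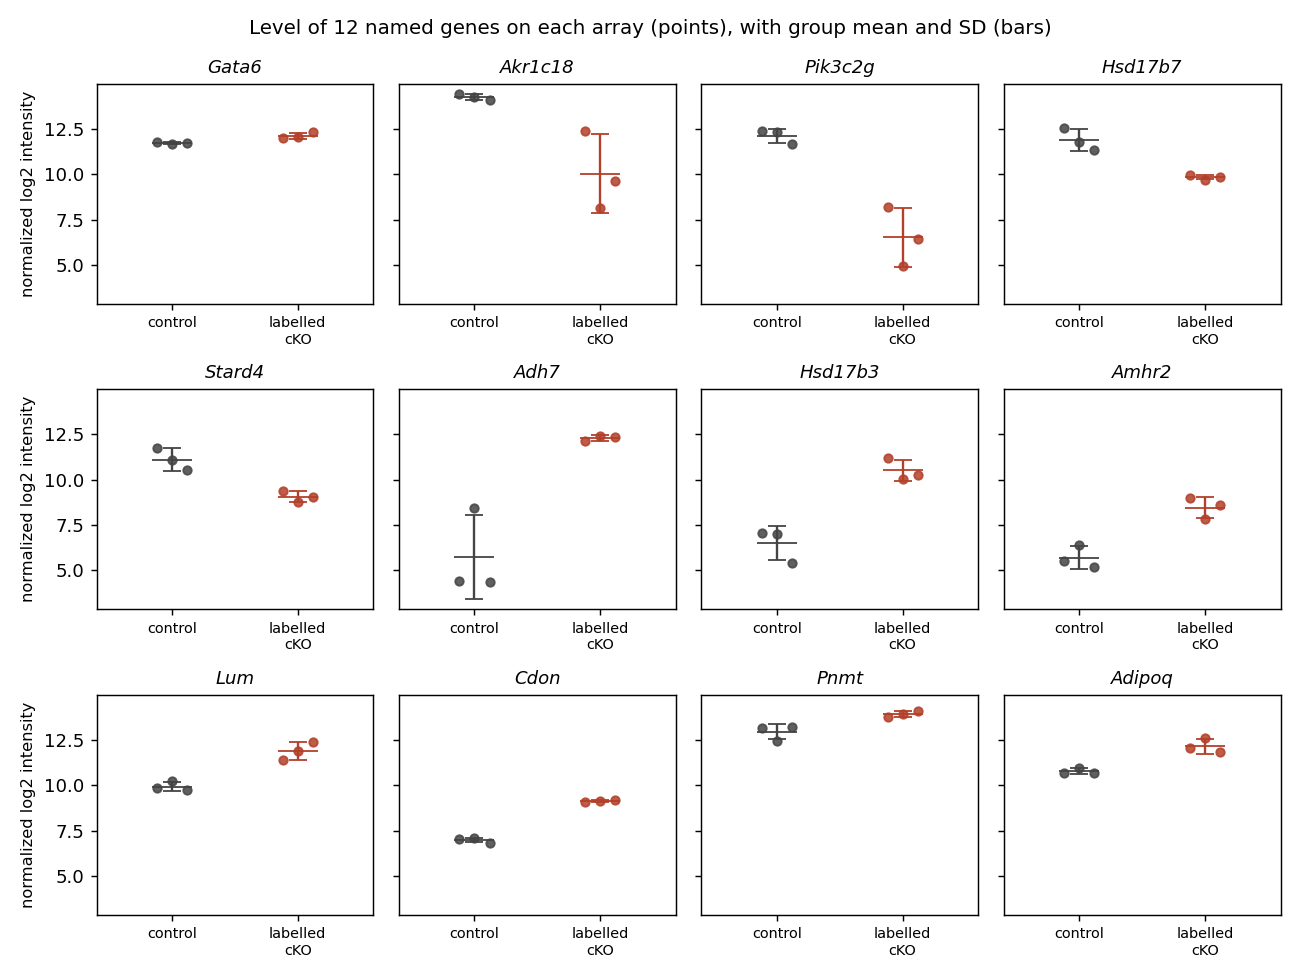
Points are the normalized log2 intensities of 12 named genes on each of the 6 arrays, with the mean and SD of each group (n = 3) as bars. Akr1c18 and Pik3c2g lie lower on all 3 arrays labelled cKO, Adh7 and Hsd17b3 higher, and Gata6 is not lower.

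Genes of cholesterol synthesis fell together. Of 20 measured, 16 fell and 0 rose over all genes tested, and 19 fell adjusted over the list alone. The median change was -1.06, and all 20 lay below 0. The steepest were Hsd17b7, a sterol reductase (-2.06, SE 0.26), the lanosterol synthase Lss (-1.88, SE 0.27) and the mevalonate pathway decarboxylase Mvd (-1.86, SE 0.30). The list was shifted down with a preset correlation (camera, adjusted p = 7.5e-15), with adjusted p = 0.239 with an estimated correlation. Relative to the control mean, the list means of the 3 arrays labelled cKO were -0.96, -1.42 and -1.06. Stard4, which carries cholesterol between membranes, fell by 2.04 (SE 0.28).

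**Figure D3:**
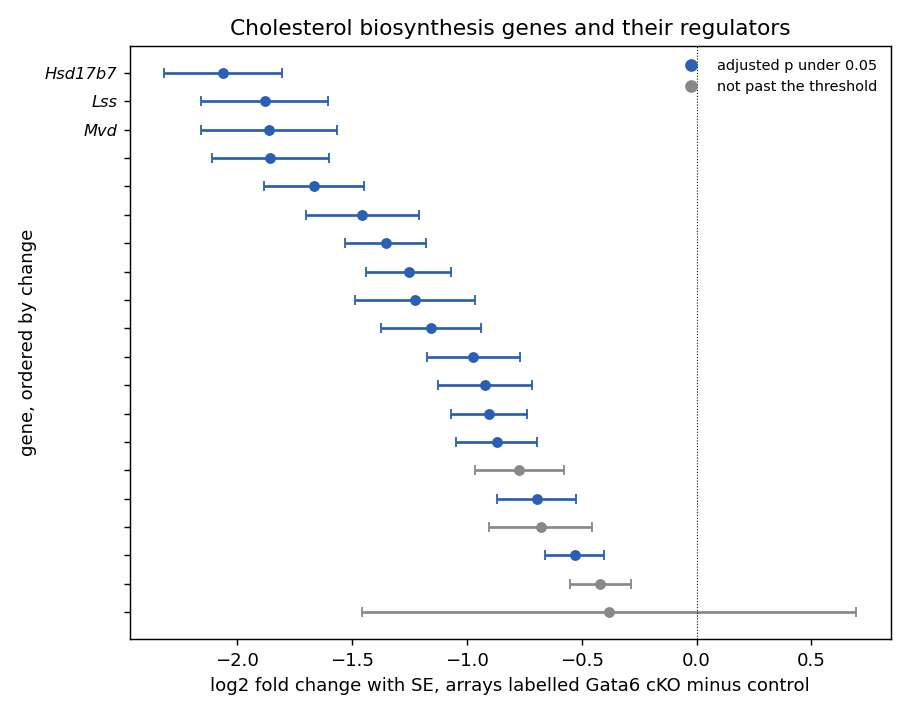
Points are log2 fold changes (arrays labelled Gata6 cKO minus control) of the 20 measured genes of the cholesterol list, which holds enzymes and regulators, with bars for the SE and names at the 3 steepest. All 20 lie below 0, and 16 pass the threshold.

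Genes that turn cholesterol into corticosteroids did not pass as a list. Of 23 measured steroidogenic genes, 3 rose and 2 fell, over all genes and adjusted over the list alone, with a median of -0.07 (camera, adjusted p = 0.729). Those that rose were Cyb5a (1.35, SE 0.12), Mc2r, the corticotropin receptor (0.54, SE 0.10), and Cyb5b (0.40, with group means of 15.02 and 15.42 near the top of the scale, where a size is uncertain), and those that fell were Stard4 and Fdxr (-0.49). A further Cyb5a probe read -0.18, and under median scaling Mc2r (0.33, adjusted p = 0.114) and Cyb5b (0.18, adjusted p = 0.299) did not pass. Star differed by -0.13 (SE 0.10) and Cyp11b1 by 0.01 (SE 0.09), neither past the threshold. Cyp21a1 did not pass either (0.03, SE 0.11), but at 15.18 to 15.49 it is near the top of the scale, where a difference may be missed. Under median scaling Cyp11b1 and Cyp21a1 lay below 0, at -0.27 and -0.13. The brightest Cyp11a1 probe differed by -0.04 (SE 0.09), whereas a further probe passed at 1.11 (SE 0.19, adjusted p = 0.00797) and others read 0.72 (adjusted p = 0.0719) and 0.14, so the probes of Cyp11a1 disagree. Nr5a1, the steroidogenic transcription factor, differed by -0.14 (SE 0.21), and Cyp17a1 was detected on 0 arrays. Among 12 genes of the aldosterone-producing zona glomerulosa, Shh rose (0.58, SE 0.12) while Agtr1b, an angiotensin receptor, and the calcium sensor Vsnl1 fell (-1.68 and -1.10). Agtr1b was detected on 2 of the arrays labelled cKO, so the size of its fall is uncertain. Adjusted over the list alone, 2 rose and 2 fell. Cyp11b2, the aldosterone synthase, read -0.95 (SE 0.35, adjusted p = 0.152). The median of this list was 0.08, against a mean of -0.17 and a downward test (camera, adjusted p = 0.737), and under median scaling the median was -0.12.

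Genes of the capsule and mesenchyme rose. Of 17 measured, 11 rose and 0 fell, 12 adjusted over the list alone, with a median of 0.74. The proteoglycan gene Lum rose by 1.94 (SE 0.23), the smooth muscle actin gene Acta2 by 1.82 (SE 0.25) and the capsular transcription factor gene Tcf21 by 1.67 (SE 0.23). The list passed with a preset correlation (camera, adjusted p = 1.0e-10) and had an adjusted p = 0.239 with an estimated correlation. Among 29 genes of the extracellular matrix, 7 rose, with Mmp2 (2.02) and Col6a2 (1.15) in front, and 2 fell, Ltbp1 (-1.68) and Sparc (-0.48). A further Col6a2 probe read 0.41 without passing (limma, adjusted p = 0.162). Adjusted over the list alone, 13 rose and 3 fell. The median was 0.32 (camera, adjusted p = 1.7e-04), with adjusted p = 0.522 with an estimated correlation.

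Lists of 3 signalling pathways passed upward with a preset correlation (camera), and each had an adjusted p = 0.239 with an estimated correlation. In the hedgehog list, 5 of 11 measured rose, over all genes and adjusted over the list alone, among them the co-receptor gene Cdon (2.14, SE 0.13), the effector Gli2 (1.70, SE 0.19) and the receptor and target gene Ptch1 (1.10, SE 0.15). In the Wnt list 4 of 20 rose, 8 adjusted over the list alone, namely the antagonist gene Sfrp1 (1.56), Fzd2 (1.27), Axin2 (0.62) and Rspo3 (0.57). Both lists had an adjusted p = 2.5e-04 (camera, preset correlation). In the list of TGF-beta, activin and BMP signalling, 4 of 27 rose, while adjusted over the list alone 9 rose and 1 fell. Its leading genes were Amhr2 (2.75), Bmp4 (0.70) and Grem1, which was detected on 0 control arrays and was at least 1.24-fold higher. A further Bmp4 probe read 0.24 without passing (limma, adjusted p = 0.486). This list had an adjusted p = 0.0104 (camera, preset correlation), and 8 of its genes lay below 0. The GATA list, of 4 measured genes with a median of 0.36, had 0 past the threshold over all genes and 2 adjusted over the list alone. It passed as a list (camera, adjusted p = 0.0268), with adjusted p = 0.507 with an estimated correlation. Its members include Gata6 itself, whose probe may check nothing, and Gata2, which is also in the mast cell list.

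**Figure D4:**
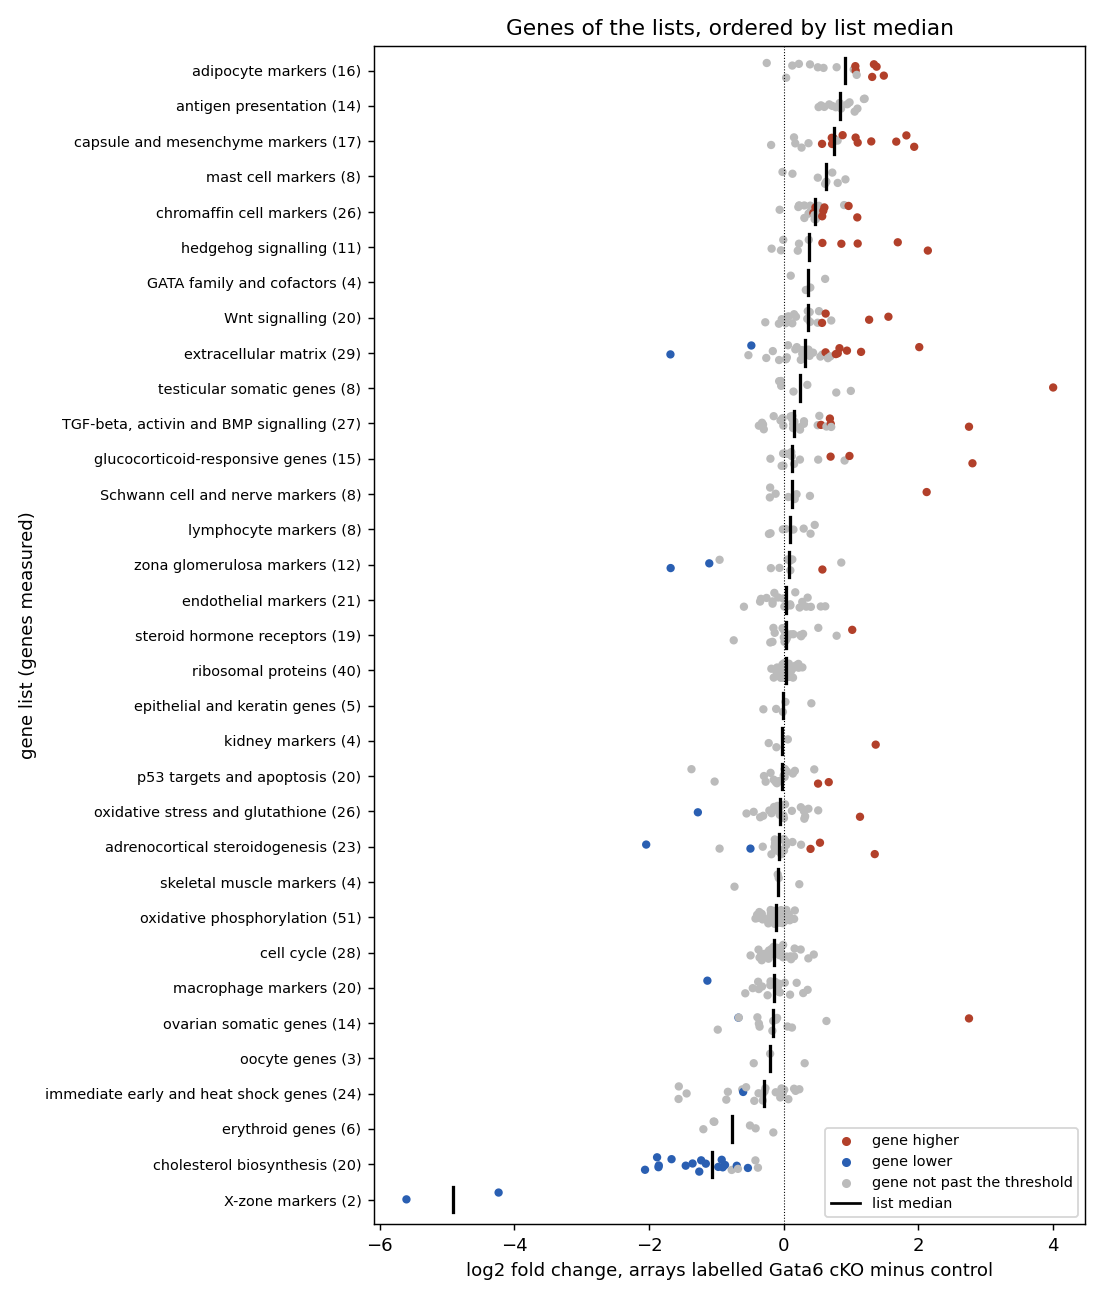
Each point is a measured gene of a list, at its log2 fold change (arrays labelled Gata6 cKO minus control), coloured where it passes the threshold, and black bars are list medians. The X-zone and cholesterol lists lie lowest, at medians of -4.92 and -1.06, and the fat cell list highest, at 0.91.

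Gonadal genes were compared as a pair of lists. Of 14 measured ovarian somatic genes, Amhr2, the receptor of anti-Müllerian hormone, rose (2.75, SE 0.36, with 3 probes from 0.86 to 2.75) and the transcription factor gene Irx3 fell (-0.67, SE 0.11). Amhr2 averaged 5.71 on the control arrays, near the background, so the size of its rise is uncertain. Adjusted over the list alone, 2 rose and 2 fell, and the list did not pass (median -0.16, camera, adjusted p = 0.293). Foxl2, a granulosa cell transcription factor, was detected on 3 control arrays and on 1 array labelled cKO. It lay near the background, so its difference of -0.15 (SE 0.18) says little. Of 8 measured testicular somatic genes, Hsd17b3 rose, over all genes and adjusted over the list alone. The testicular median was 0.25 (camera, adjusted p = 0.0601), and it exceeded the ovarian median by 0.41 with an SE of 0.68. The lists shared 3 genes, of which 0 were measured. Lhcgr, the luteinizing hormone receptor gene, was detected on 2 arrays labelled cKO and on 0 control arrays and was not tested.

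Markers of chromaffin, fat and mast cells had upward medians on the arrays labelled cKO. Chromaffin cells of the medulla were represented by 26 genes, of which 7 rose, 19 adjusted over the list alone, with a median of 0.47. They included the peptide gene Cartpt (1.09, SE 0.17), Pnmt, which makes adrenaline (0.97, SE 0.19), and Syp (0.61, SE 0.15). Th read 0.48 higher and Chga 0.39 higher, without passing. Of 16 fat cell genes, 6 rose, 9 adjusted over the list alone, with a median of 0.91. They included Cidec (1.49), the adiponectin gene Adipoq (1.38) and the lipase gene Lpl (1.34). The fat list mean lay 0.70, 1.37 and 0.22 above the control mean on cKO replicates 1, 2 and 3, and control replicate 3 lay 0.16 above it. Both lists passed with a preset correlation (camera, adjusted p = 8.6e-11 and 2.7e-06), with adjusted p = 0.323 and 0.476 with an estimated correlation. Of 8 mast cell genes, 0 passed over all genes and 6 rose adjusted over the list alone, with a median of 0.63 (camera, adjusted p = 0.00295), and adjusted p = 0.239 with an estimated correlation. Of 6 erythroid genes, 0 passed either way, that is over all genes or adjusted over the list alone, with a median of -0.76 (camera, adjusted p = 0.0350), and adjusted p = 0.507 with an estimated correlation. The median was -0.41 without control replicate 1 and -0.46 with detection required on all arrays at a p under 0.01. The 10 tested probes of the globin gene Hbb-b1 read from -1.02 to -0.15, and the brightest, at 15.80 on 2 arrays, is near the top of the scale. Of 14 antigen presentation genes 0 passed either way. Their median was 0.84 (camera, adjusted p = 0.00217), with adjusted p = 0.701 with an estimated correlation. Their mean lay 2.29 above the control mean on cKO replicate 1 and 0.03 and 0.25 above it on the others labelled cKO, and without cKO replicate 1 the median was 0.13 (adjusted p = 0.422). B2m read 0.56 higher without passing.

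Endothelial genes did not pass as a list (21 measured, 0 passed either way, median 0.03, -0.06 under median scaling, camera adjusted p = 0.822). The vascular sialomucin gene Emcn differed by 0.10, and by -0.10 under median scaling. Of 20 macrophage genes, 1 fell, Cd68 (-1.13, SE 0.16), over all genes and adjusted over the list alone (median -0.15, camera, adjusted p = 0.101). Without cKO replicate 1 the macrophage median was -0.34 (adjusted p = 3.0e-04), and without control replicate 3 it was -0.27 (adjusted p = 0.00944), so the list passed downward in both. Of 8 lymphocyte genes 0 passed either way (median 0.09, adjusted p = 0.729), and Coro1a read 0.30 higher. The Schwann cell and nerve list had 1 of 8 genes higher in both counts, with a median of 0.12 (adjusted p = 0.535). The kidney list had 1 of 4 higher in both counts, the water channel gene Aqp1 (1.37, SE 0.17), with a median of -0.02, 0.02 under median scaling, against an upward test (adjusted p = 0.680). Of 3 oocyte genes (median -0.20, adjusted p = 0.859), with Gdf9 at -0.44, and of 5 epithelial and keratin genes (median -0.01, adjusted p = 0.996), with Upk3b at 0.41, 0 passed either way. Of 4 skeletal muscle genes, 0 passed over all genes and 1 fell adjusted over the list alone (median -0.08, adjusted p = 0.675), with Myl1 at 0.23.

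Among the lists of cell state, that of oxidative phosphorylation lay slightly lower, with 40 of 51 genes below 0 and a median of -0.11, although 0 passed over all genes or adjusted over the list alone. Its brightest gene, Atp5b, at 15.42 to 15.65, is near the top of the scale, so its difference of -0.14 says little. It passed as a list (camera, adjusted p = 0.00217), with adjusted p = 0.507 with an estimated correlation. Of 24 immediate early and heat shock genes, Jun fell (-0.60, SE 0.15, adjusted p = 0.0479), 0 passed adjusted over the list alone, and the median was -0.30 (camera, adjusted p = 0.0209), with adjusted p = 0.642 with an estimated correlation. The list means of the control arrays ranged from -0.58 on replicate 1 to 0.49 on replicate 3 around their own mean, and without control replicate 3 the median was -0.19 (adjusted p = 0.401) and without cKO replicate 1 it was -0.21 (adjusted p = 0.0704). Of 15 glucocorticoid-responsive genes, 3 rose both over all genes and adjusted over the list alone, Lcn2, the chaperone gene Fkbp5 (0.98, SE 0.16) and Sult1a1 (0.70, SE 0.10). The median was 0.12 (camera, adjusted p = 0.0178), with adjusted p = 0.239 with an estimated correlation, and it was 0.04 under median scaling. The remaining lists did not pass. Of 19 steroid hormone receptor genes Nr1h3, an oxysterol receptor gene, rose (1.02, SE 0.20), with 1 higher and 1 lower adjusted over the list alone (median 0.03, adjusted p = 0.395). A further Nr1h3 probe read 0.22 without passing (limma, adjusted p = 0.556). Of 20 genes of p53 targets and apoptosis, Phlda3 (0.67) and Sesn1 (0.51) rose in both counts (median -0.03, adjusted p = 0.979). Of 26 genes of oxidative stress and glutathione, Gstt1 rose (1.13) and Gsta3 fell (-1.27), in both counts (median -0.06, adjusted p = 0.883). Of 28 cell cycle genes 0 passed either way (median -0.14, adjusted p = 0.395), and Mcm4 read 0.25 higher. Without cKO replicate 1 the cell cycle list passed downward (median -0.25, adjusted p = 0.0191). Of 40 ribosomal protein genes 0 passed either way. Their median was 0.03 (adjusted p = 0.225), but it was -0.20 under median scaling, where the list passed downward (adjusted p = 3.0e-04), and 0.06 without cKO replicate 2, where it passed upward (adjusted p = 0.00687). Rplp1, at 15.75 to 15.80, is near the top of the scale, so its difference of -0.02 says little.

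In all, 15 of 32 tested lists passed with a preset correlation, 11 upward and 4 downward. With an estimated correlation 0 passed, 5 reached an unadjusted p under 0.05, and the directional fry test passed 8, of which 7 are among the 15 and the other is the testicular list. Under median scaling the GATA, glucocorticoid and erythroid lists did not pass (adjusted p = 0.0515, 0.0635 and 0.0515). Without control replicate 3 or cKO replicate 3 the GATA list did not pass (0.0507 and 0.0585), and the erythroid list did not pass without control replicate 1 or 2 or cKO replicate 1 or 2 (0.0680, 0.0510, 0.140 and 0.0982). With detection required on all arrays at a p under 0.01, the TGF-beta, glucocorticoid and erythroid lists did not pass (0.0701, 0.09995 and 0.0996), nor did the erythroid list without an intensity trend (0.0531). With a robust variance Adh7, Akr1c18, Cidec, Gpnmb, Hamp, Ibsp, Lpl and Spp1 did not pass, at adjusted p-values from 0.0670 to 0.139. Of the genes named, Axin2, Bmp4, Cidec, Cyb5b, Grem1, Jun, Lpl, Ltbp1, Nr1h3, Pnmt, Rspo3, Sesn1, Shh and Syp each kept their direction but did not pass without at least 1 array, at adjusted p-values from 0.0561 to 0.165. With all arrays, calls were also lost under median scaling for Grem1, Rspo3, Sesn1 and Syp (adjusted p = 0.0593 to 0.0906), with the replicate number as a block for Axin2, Cyb5b, Grem1, Jun, Rspo3, Sesn1 and Shh (0.0508 to 0.0734) and without an intensity trend for Axin2, Cyb5b, Jun, Lpl, Rspo3, Sesn1, Shh and Syp (0.0596 to 0.0835). They were lost with the mean of a gene's probes for Bmp4, Jun, Sesn1 and Syp (0.0505 to 0.115), without a filter for Grem1, Jun, Rspo3 and Syp (0.0545 to 0.0661), with a background fitted to the signals for Jun, Rspo3 and Syp (0.0511 to 0.0526), and without background correction or with the deposited matrix for Grem1 (0.0698 and 0.0696).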

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

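The alternatives were fixed before the data were examined, except a covariate for cholesterol genes. The 930 changed genes became between 769 and 1271 under other backgrounds, scalings, filters, variance models, array weights and probe rules. Leaving out 1 array gave 398 to 960, with 253 to 608 higher and 145 to 352 lower. The counts were 601 without control replicate 1, 439 without control replicate 2, 502 without cKO replicate 2 and 398 without cKO replicate 3, where fewer samples entered the test. Genes lower numbered 602 under median scaling, against 352, and the cause was not tested. With the replicate number as a block 721 genes were called, 653 of them shared. Same-numbered arrays deviated with r of 0.044, 0.036 and -0.015, and not every array correlated best with its own number. Gata6 stayed higher throughout, by 0.30 to 0.46 without 1 array and by 0.21 under median scaling (adjusted p = 0.230). It passed with a robust variance (0.40, adjusted p = 0.0472), with array weights (0.43, 0.0330) and without cKO replicate 1 (0.46, 0.0448), over a range from 0.0330 to 0.230. The causes were not tested. Of the 32 lists 15 passed, against 0 with an estimated correlation and 8 by fry (7 of them among the 15), tests built on another error, and 14 to 16 without 1 array. The testicular list (median 0.25) passed under median scaling (0.27, adjusted p = 0.0357), without a filter (0.059, 0.0087), with the replicate block (0.25, 0.0436), by fry (0.25, 0.0279), without control replicate 2 (0.30, 0.0434) and without cKO replicate 2 (0.28, 0.0260). Its median was 0.22 to 0.30 without 1 array. It did not pass with an estimated correlation (adjusted p = 0.323). With detection on all arrays at a p under 0.01 it did not pass, at a median of 0.055 (adjusted p = 0.625), and the cause was not tested. The ovarian median (-0.16) was -0.24 to -0.09 without 1 array, -0.36 with that detection rule, -0.29 without background correction or with the deposited matrix, -0.10 without a filter and -0.075 with a background fitted to the signals, and the list did not pass in any of these. Ribosomal protein genes, at 0.03, fell under median scaling (-0.20, adjusted p = 3.0e-04), and the cause was not tested. Of 58 changed named genes 39, and of 15 lists 9 (leaving aside those list tests), passed under each alternative run. Array weights and the robust variance did not enter the list tests, and a slide block was not run. Dim probes lie near the background, so their changes are understated.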

Other observations

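The tests of a changed share of cortical cells, of normalization, of the second chromaffin list, of the Gata6 labels and of the Gata6 neighbours were chosen after the results they bear on had been seen, and so were the gene groups of the next paragraphs.

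Histone genes lay lower on the arrays labelled cKO. Of 42 measured, 36 lay below 0, 11 fell and 0 rose, with a median of -0.32 and of -0.47 under median scaling (camera, p = 6.2e-10, and p = 0.193 with an estimated correlation). This family and the interferon genes below were chosen after their values had been seen. The camera p-values of both groups therefore describe them and do not test them. H4c8 fell by 0.58 (SE 0.09), H2bc14 by 0.52 (SE 0.10) and H2bc6 by 0.41 (SE 0.07), each lower on 3 of 3 arrays. H2bc6 did not pass without control replicate 2 (adjusted p = 0.0539) or without an intensity trend (0.0554), and H2bc14 passed only without cKO replicate 1 among the fits that left out 1 array (adjusted p = 0.0559 to 0.0883 otherwise). Copies of these genes are nearly identical, so their probes are not independent. Other changed genes outside the lists, named after their values were seen, were the epimerase gene Rpe, detected on 0 control arrays and at least 4.23-fold higher, Cyp2e1 (2.25, SE 0.32), Ces3 (1.78, SE 0.35, but adjusted p = 0.0558 to 0.0714 without any 1 control and 0.109 with a robust variance), the angiogenesis inhibitor gene Serpinf1 (1.47, SE 0.14) and the chemokine gene Cxcl14 (1.00, SE 0.14).

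Interferon response genes stood apart on 1 array. On cKO replicate 1 the mean of 18 such genes lay 2.37 above the control mean, against -0.08 and 0.14 on the others labelled cKO, and 0 of 18 passed (limma, median 0.82, camera p = 7.3e-04, and p = 0.425 with an estimated correlation). The proteasome gene Psmb8 read 14.16 there and 10.88 to 11.10 on the other 5 arrays. The guanylate binding gene Gbp2b ran otherwise, at 8.71 to 9.83 on the control arrays, 9.15 on cKO replicate 1 and 4.61 and 4.80 on the others. Ucp1, a marker of brown fat, read 10.83, 12.35 and 7.66 on the arrays labelled cKO and 10.18 to 10.94 on the controls. The immediate early gene Fos read 6.31 on control replicate 1 and 9.48 and 9.64 on the other controls.

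The count of 930 changed genes and of 15 shifted lists came from 1 of the 10 ways to split 6 arrays into 3 and 3. The highest of the other splits gave 1 gene and 13 lists, and 1 of 10 splits reached each count. With 10 splits the share cannot fall under 0.05, so no more can be said of chance. Every other split gave between 4 and 13 lists, so the list test with a preset correlation calls many lists under other groupings too, which weakens each list call taken alone.

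Lower cholesterol genes were weighed first. A smaller share of cortical cells would lower steroidogenic genes alike, but their median exceeded that of the cholesterol list by 0.99 (SE 0.21, over genes). Cholesterol genes had an estimated correlation of 0.51, so this SE may be too small. The steroidogenic gene Cyp21a1 is near the top of the scale, where a fall may be missed. The medians argue against a smaller cortical share as the whole of the cholesterol fall. They cannot exclude that it accounts for part, and a larger medullary share, weighed below, would go with a smaller cortical one. Relative to the control mean, list means of steroidogenic genes were -0.06, -0.09 and -0.12 on the 3 arrays labelled cKO. Those of cholesterol genes were -0.96, -1.42 and -1.06. Under 4 other background corrections and normalizations the cholesterol median stayed at or below -0.80. Only median scaling departed from quantile normalization, since the deposited values also matched the mean of the sorted signals in the 1 column compared. The argument against the scaling therefore rests on that setting alone. With the immediate early mean of each array as a covariate the median was -1.32 and 14 of 20 genes passed, which argues against handling stress as far as those genes read it. The deletion of Gata6 and a loss of X-zone cells with their own sterol demand stay open, and a change of regulation downstream of the deletion is a hypothesis that these data do not test.

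Higher markers of cells outside the cortex were weighed next. A smaller share of cortical cells would raise markers of cells outside the cortex alike. The capsule median exceeded the larger of the endothelial and macrophage medians by 0.71 (SE 0.20, over genes). Endothelial cells and macrophages may lie within the cortex too, so this difference cannot decide whether the cortical share was smaller. For the medulla, a second list of 20 neuroendocrine genes, in which the value of Syt4 had been seen before, had a median of 0.28 (SE 0.10), with 3 higher and 0 lower (camera p = 0.00181, and p = 0.0519 with an estimated correlation). This is in line with a larger medullary share in the arrays labelled cKO. A second list of 13 fat genes had a median of -0.051 (SE 0.25), and its mean lay 0.58 above the control mean on cKO replicate 2 and at 0.02 and -0.06 on the others labelled cKO, so fat attached to the glands cannot be told apart from a change within them.

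The Gata6 signal that was not lower was weighed last. All 6 arrays correlated best with an array of their own label, which argues against 1 exchanged label. The array carries 1 Gata6 probe, and its place relative to the deleted part is not given, so a probe outside that part may account for the signal. An exchange of both whole groups cannot be told apart by the Gata6 difference of 0.40 (SE 0.10), since the share of Gata6-expressing cells that lost the gene is not known. The X-zone markers argue against such an exchange, as far as they read this zone of virgin females. Akr1c18 read 14.28 (SD 0.16) on the control arrays and 10.04 (SD 2.16) on those labelled cKO. Pik3c2g read 12.12 (SD 0.40) and 6.52 (SD 1.61). With exchanged labels, unmodified virgin females would be the ones low in both markers.

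Variants carried along with the Gata6 locus were tested through its neighbours. Of the 40 measured genes nearest to Gata6 in GRCm38.p6, 0 changed, against 7.17% elsewhere (Fisher's exact test, two-sided, p = 0.114). The upper 95% bound of the odds ratio was 1.25, so an excess of changed genes there was not seen and a small one cannot be ruled out.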
